A study of Arabidopsis thaliana with 15 samples.

How the data were processed

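Gene expression was measured by bulk MARS-seq, a 3'-end RNA sequencing protocol, in whole seedlings of Arabidopsis thaliana (ecotype Col-0, 2 weeks old). Per the labels, the 15 libraries fell into 5 groups of 3: untreated controls and seedlings given cercosporin at 0.1, 1, 10 or 100 µM. Cercosporin is a light-activated toxin of Cercospora fungi. Per the labels' protocols, treated seedlings stood in the toxin in darkness for 1 h, were washed 3 times and then stood in light of 30 µE for 30 min. The control plates stayed in light throughout. Each comparison with the controls therefore holds the toxin, the light regime and any difference in soaking and washing together. Comparisons between doses share 1 light regime. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

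Per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.17.1.14, trimmed with cutadapt 1.8.3, aligned with STAR and assigned to genes with HTSeq. The genome build and the annotation are not given in the sources used here, and neither is whether counting used strand. Per the file headers, the deposited table holds raw counts without filtering on unique molecular identifiers, so counts include amplification copies. The authors' normalized columns are a signal scale, the raw counts divided by 1 size factor per library, and the authors' regularised values are on a log2 scale. The deposited table also holds the authors' DESeq2 log2 fold changes, p-values and adjusted p-values for the group pairs. The group names in those comparisons are numbered differently from the doses. Each was matched to the labelled groups by the deposited fold changes: the group named 0 held the libraries labelled 100 µM, 1 those of 1 µM, 2 those of 0.1 µM, 3 the controls and 4 those of 10 µM. These numbers follow the order of the sample codes and not that of the doses. Numbers in code order need not stand for a dose, so they do not by themselves contradict the labels. Whether the labels are right cannot be checked from the sources used here. Wrong labels could change what the values of any group stand for, the controls and 100 µM included. The grouping used here follows the labels of each sample, and the table held 0 other columns of per-sample values.

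The raw counts of 14190 genes were analysed. Library totals lay between 834190 (1 µM replicate 2) and 4554702 (10 µM replicate 3). Gene symbols came from the TAIR10.1 table of the reference, which matched 14103 identifiers; the remaining genes of the organelle genomes keep their identifiers. No coordinates are printed, because the build of the counts is not given. The reference served also to find genes with a near-identical copy, defined as an alignment (blastn 2.17.0) of at least 75 bases at 90% identity or more between the last 500 bases of their transcripts, and genes whose 3' end lies inside another gene.

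Testing used edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter by group, which left 10374 genes, and quasi-likelihood tests with a group term over all 15 libraries. Benjamini-Hochberg adjustment was applied over the genes tested, with a threshold of 0.05. Each gene called higher or lower passed that threshold; fold changes are edgeR estimates on the log2 scale, given with their standard error. Levels are CPM, counts scaled to the TMM-adjusted total of the library, with mean and SD over the 3 libraries of a group. The dose trend was the slope on log10 dose over the 12 treated libraries, with 10666 genes tested. A joint test of the 4 doses gave the number of genes with any difference. The biological coefficient of variation was 20.6%.

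A total of 21 gene lists were fixed from textbook knowledge before the data were examined, as were the designs, the thresholds and most alternatives. The lists cover singlet oxygen markers, antioxidant enzymes and ferritins, xenobiotic detoxification, heat shock, jasmonate, ethylene and ERF factors, salicylate and immune response, mitochondrial dysfunction, abscisic acid with dehydration and cold, touch and calcium, nuclear photosynthesis genes, cytosolic ribosomal proteins, auxin, dark and starvation, acute light response, the circadian clock, endoplasmic reticulum stress, senescence and cell death, flavonoid synthesis, the mitotic cell cycle and root markers. Some genes stand on more than 1 list, LOX3, LOX4, ERF4, ERF5, ERF6 and CHS among them. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with fry. Of the 7 mitotic genes, 1 passed the filter, so that list was not tested. Members were counted by the edgeR test over all genes and adjusted over the list alone. List p-values were adjusted together over the 4 doses against the controls, and separately for the dose comparisons with the trend.

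The genes to be named were set by a rule: for each dose against the controls and for 100 against 0.1 µM, up to 6 rises and 6 falls with the largest change among genes past the threshold, with a mean log2 CPM of at least 4 and no overlap between the replicates of both groups. Up to 4 members of each list passing the camera test were added, and all tested singlet oxygen markers. Some genes that met the rule are not reported here. Any other gene named outside a list was chosen after its values were seen.

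The pipeline was tested on simulated counts, with 200 of 10374 genes changed. For 1 µM against the controls, edgeR recovered 20% of genes changed 2-fold and 72% of those changed 4-fold, with 2 wrong calls among 94. For 10 µM the shares were 37% and 81%, with 5 wrong calls among 123. For 100 µM they were 32% and 84%, with 4 wrong calls among 120. For the dose trend, slopes of 0.5 and 1 were recovered in 71% and 96% of genes, with 10 wrong calls. In a simulated list test for 1 µM, the changed list gave p = 9.04e-12 by camera, 2.19e-05 with an estimated correlation and 3.39e-07 by fry. Of 100 unchanged lists, camera called 1, camera with an estimated correlation 0 and fry 8, at an unadjusted p under 0.05. The simulated genes varied independently of each other and the lists were random. These shares therefore do not give the error rate for lists whose members vary together.

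The alternatives were other normalization factors (RLE, upper quartile), other filters on low counts (none, or at least 10 counts in 3 samples), DESeq2 1.42.0, limma-voom, the replicate number as a block, each replicate left out in turn, organelle genes left out, the compared pair of groups alone, and the leading digit of the sample code as a term. Further alternatives were added after the data had been seen: libraries thinned to the smallest total, the spread taken from the 12 libraries other than 100 µM, the trend without 100 µM, and genes with a near-identical copy left out. The sample codes began with 7, 8 or 1: controls 7, 7 and 8, 0.1 and 1 µM all 7, 10 µM all 8 and 100 µM all 1. What the digit stands for is not given in the sources used here, and it cannot be separated from the 100 µM group. Comparisons of 10 µM with 0.1 and 1 µM coincide with the digit as well, and only the controls hold both 7 and 8. The effect of the digit is thus estimated from the controls, 2 libraries with 7 and 1 with 8. With the term, every comparison of 10 µM depends on that 1 control library, so lost calls do not by themselves show an effect of the digit. The digit term was fitted without the 100 µM libraries, so its counts are set beside those of the 12-library fit. Its use for the comparisons among 0.1, 1 and 10 µM was added after the data had been seen.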

Results

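Whole Arabidopsis seedlings were profiled by 3'-end RNA sequencing at 4 cercosporin doses and in untreated controls, with 3 libraries per group. Cercosporin produces singlet oxygen and other reactive oxygen in light, and the dose series addresses how seedling transcripts differ with the amount of toxin. Totals were 1689357 to 2243950 counts in the controls, 2613168 to 3564426 at 0.1 µM, 834190 to 3061276 at 1 µM, 1574746 to 4554702 at 10 µM and 1044626 to 2922199 at 100 µM. Between 12127 and 13865 genes had at least 1 count per library.

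The libraries labelled 100 µM stood apart from all others. The first principal component, with 51% of the variance, placed them at 74.4 to 104.9 and every other library between -32.4 and -13.7. The second component, with 11.2%, put replicate 1 of that group at 59.7 and replicates 2 and 3 at -41.9 and -30.8. The third component, with 6.2%, set replicate 2 of 1 µM, the smallest library, at -52.3 and the others between -7.3 and 17.1. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.945 to 0.974 within the other groups and 0.881 to 0.952 within 100 µM. Within each group, replicates differed in every pair by more than counting error (chi-square), which is all that this comparison covers.

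**Figure D1:**
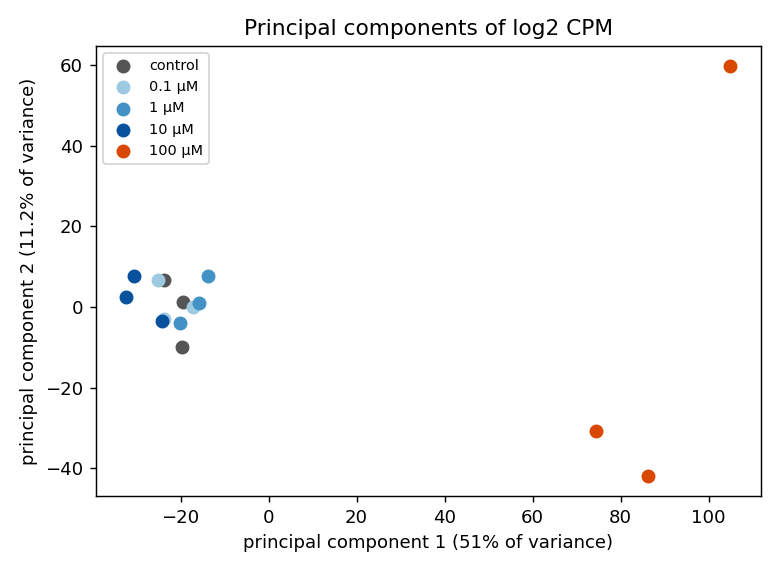
First and second principal components of log2 CPM (arbitrary units), 1 point per library, coloured by group (control, 0.1, 1, 10 and 100 µM cercosporin). The 3 libraries labelled 100 µM lie at 74.4 or more on the first component and the other 12 at -13.7 or less.

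At 100 µM, single transcripts of jasmonate synthesis and of senescence were among those far from their control level. LOX3 (AT1G17420), a lipoxygenase of jasmonate synthesis, fell from 178 ± 22.8 CPM to 16.1 ± 4 CPM (SD, n = 3 per group), a log2 change of -3.41 ± 0.21. NAP (AT1G69490), a NAC transcription factor that promotes leaf senescence, stood at 14.9 ± 6.3 CPM against 0.154 ± 0.266 CPM in the controls, where no library held more than 1 count. PIP3 (AT4G35100), an aquaporin, rose from 8.69 ± 2.37 to 154 ± 37.8 CPM. DDF1 (AT1G12610), a DREB-type transcription factor, fell from 73.5 ± 20.4 to 1.9 ± 1.66 CPM.

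The largest rises by the fixed rule were those of AT3G15450 (log2 change 4.48 ± 0.25), PIP3 (4.12 ± 0.24), the thylakoid protein PSI-P (3.85 ± 0.24), DI19 (3.83 ± 0.25), the glutamate dehydrogenase GDH2 (3.77 ± 0.32) and the photosystem I subunit gene PSAF (3.69 ± 0.24). The largest falls were those of the chloroplast gene ATCG00640 (-6.12 ± 0.5), DDF1 (-4.96 ± 0.42), ERF13 (-4.13 ± 0.41), AT1G22810 (-4.04 ± 0.44), AT1G78070 (-3.95 ± 0.43) and AT2G35290 (-3.9 ± 0.21). The edgeR adjusted p-values of these 12 genes lay between 1.31e-09 and 1.91e-06, and the replicates of both groups did not overlap for any of them.

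Of 15 singlet oxygen markers, genes known from the flu mutant, 7 fell and 0 rose at 100 µM (10 and 0 adjusted over the list alone). Those that fell were LOX3, LOX4 (-2.96 ± 0.25), FLOT3 (-2.06 ± 0.37), OM66 (-1.54 ± 0.41), WRKY40 (-0.92 ± 0.27), ZAT12 (-0.79 ± 0.21) and ERF4 (-0.58 ± 0.13). The remaining 8 did not pass: BAP2 (-1.78 ± 0.73), SIB1 (-1.33 ± 0.54), ZAT10 (-0.52 ± 0.21), WRKY33 (-0.51 ± 0.29), ERF5 (-0.46 ± 0.37), ERF6 (-0.36 ± 0.27), BAP1 (-0.18 ± 0.25) and the AAA ATPase gene AT3G28580 (-0.06 ± 0.4). Camera placed the list lower (adjusted p = 0.00131, adjusted p = 0.589 with an estimated correlation).

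Among 18 jasmonate genes, 10 fell and 2 rose at 100 µM (10 and 3 adjusted over the list alone; camera lower, adjusted p = 0.0136, adjusted p = 0.416 with an estimated correlation). Falls included the OPDA reductase gene OPR3 (-1.91 ± 0.18), JAZ5 (-2.78 ± 0.36) and CYP94B3 (-2.11 ± 0.17), which hydroxylates the active hormone. The rises were LOX2 (0.82 ± 0.3) and ORA59 (1.87 ± 0.3). Senescence and cell death genes rose in 4 of 6 cases with 0 falls (4 and 0 adjusted over the list alone, adjusted p = 0.027, adjusted p = 0.416 with an estimated correlation), namely NAP, NAC092, the ribonuclease RNS1 (3.27 ± 0.36) and the metacaspase MC2 (0.99 ± 0.33).

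Endoplasmic reticulum stress genes rose in 4 of 10 cases with 0 falls (6 and 0 adjusted over the list alone; camera higher, adjusted p = 0.0276, adjusted p = 0.648 with an estimated correlation). They were the protein disulfide isomerase PDIL1-1 (2.85 ± 0.45), BZIP60 (2.37 ± 0.45), ERDJ3B (0.87 ± 0.27) and the calnexin CNX1 (0.8 ± 0.16). Dark and starvation genes rose in 5 of 6 cases with 0 falls (5 and 0 adjusted over the list alone; camera higher, adjusted p = 0.022, adjusted p = 0.416 with an estimated correlation), with DIN4 at 2.52 ± 0.43 and DIN3 at 1.79 ± 0.37. The treated seedlings had a dark step that the controls did not have.

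Other lists moved in both directions at 100 µM and did not pass the camera test. Of all 10374 genes tested, 1875 were higher and 1517 lower at this dose. Calls within a list are therefore not by themselves particular to that list. Photosynthesis genes rose in 12 and fell in 3 of 38 cases (12 and 3 adjusted over the list alone, adjusted p = 0.0624), with PSAF and PSAH2 (3.62 ± 0.28) far above the list's median of 0.13. Ribosomal protein genes rose in 4 and fell in 11 of 24 cases (4 and 11 over the list alone, adjusted p = 0.0968), from RPL9C at 2.86 ± 0.55 down to RPL3A at -1.28. Salicylate and immune genes rose in 5 and fell in 6 of 22 cases (5 and 6 over the list alone, adjusted p = 0.886). WRKY70 was at 4.21 ± 0.66 and PAD4 at 1.88 ± 0.37, and the list's median of -0.24 and mean of 0.15 differed in sign. Abscisic acid, dehydration and cold genes rose in 2 and fell in 4 of 15 cases (2 and 4 over the list alone, adjusted p = 0.326), with COR15A at 2.68 ± 0.37 and ERD10 at -2.65 ± 0.14. Ethylene and ERF genes rose in 2 and fell in 3 of 13 cases (2 and 3 over the list alone, adjusted p = 0.286).

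Clock genes rose in 4 of 6 cases with 0 falls (5 and 0 adjusted over the list alone, adjusted p = 0.0523), GI at 1.08 ± 0.2 among them. Antioxidant genes rose in 4 and fell in 3 of 14 cases (6 and 3 over the list alone, adjusted p = 0.898), with CSD2 at 0.81 ± 0.19 and 2CPA at -0.8 ± 0.19. Detoxification genes rose in 3 and fell in 4 of 20 cases (3 and 4 over the list alone, adjusted p = 0.269). Heat shock genes rose in 1 and fell in 2 of 16 cases (1 and 2 over the list alone, adjusted p = 0.543). Auxin genes fell in 2 of 3 cases (2 over the list alone, adjusted p = 0.128), with IAA19 at -2.73. Touch and calcium genes rose in 1 and fell in 2 of 4 cases (1 and 2 over the list alone, adjusted p = 0.464), mitochondrial dysfunction genes fell in 1 of 6 (1 over the list alone, adjusted p = 0.439), and root markers rose in 4 of 12 (4 over the list alone, adjusted p = 0.246). Acute light genes (3 tested, adjusted p = 0.702) and flavonoid genes (5 tested, adjusted p = 0.969) held 0 calls by edgeR over all genes, 0 over the list alone.

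The fry test asks whether the members of a list moved in 1 common direction, and not whether they moved more than other genes. It called 8 lists at 100 µM, where camera called 5. Among lists that camera did not call, it placed clock genes higher (adjusted p = 0.000101) and auxin genes (0.000405), abscisic acid, dehydration and cold genes (0.00136) and ribosomal protein genes (0.0452) lower. The endoplasmic reticulum stress list was called by camera alone. Fry called 5 lists at 1 µM, all of them also called by camera, and 0 at 0.1 and 10 µM, where camera called 6 and 3. The mixed form of fry, in which members may move either way, called 15 of 20 lists at 100 µM and 5 at 1 µM. At 0.1 and 10 µM the mixed form called 1 list each.

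In total 3392 of 10374 genes differed between 100 µM and the controls, 1875 higher and 1517 lower, of which 1383 and 941 changed at least 2-fold. The count was 1364 with all libraries thinned to the smallest total and 2223 with only these 2 groups in the fit. Chloroplast genes took 0.221% ± 0.0234 of counts at 100 µM against 0.468% ± 0.0203 in the controls, and mitochondrial genes 0.356% ± 0.0709 against 1.02% ± 0.15 (SD, n = 3 per group; exact two-sided permutation p = 0.1 for both, the smallest that 3 against 3 allow; Benjamini-Hochberg adjusted over 8 tests, 0.267). At 0.1, 1 and 10 µM the chloroplast share was 0.473%, 0.501% and 0.576%, and the mitochondrial share 1.17%, 1.1% and 1.04%. The chloroplast share at 10 µM, which lay above that of the controls, had the same permutation p = 0.1 (adjusted 0.267). These shares were planned as a sign of RNA quality and library composition, so they need not stand for organelle expression.

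**Figure D2:**
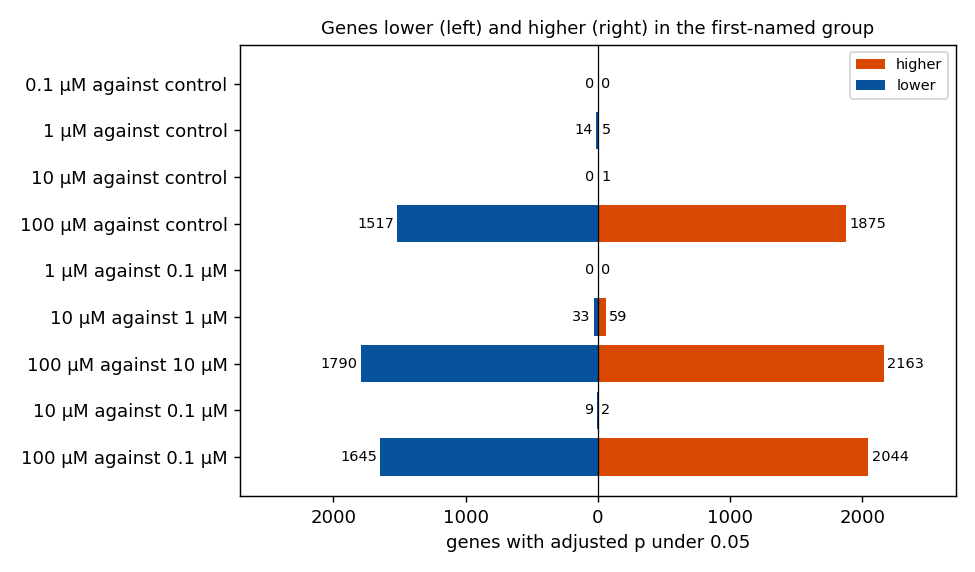
Genes with an edgeR adjusted p under 0.05 in each comparison; bars to the left count genes lower and bars to the right genes higher in the first-named group. The comparisons with 100 µM call 3392 to 3953 genes and the others 0 to 92.

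At 1 µM, 4 light-harvesting transcripts stood above the controls and 4 of 18 jasmonate transcripts below them. LHCB1.1 (AT1G29920), a chlorophyll a/b binding protein gene, rose from 693 ± 76.5 to 2770 ± 590 CPM (SD, n = 3 per group; log2 change 2.00 ± 0.21, adjusted p = 0.000166). LHCB2.1 (1.41 ± 0.21), LHCB2.2 (1.31 ± 0.20) and LHCB1.2 (0.91 ± 0.18) rose as well, as did PIP3 (1.33 ± 0.26). CYP94B3 (AT3G48520) fell from 167 ± 30.5 to 70 ± 4.73 CPM (-1.26 ± 0.17, adjusted p = 0.00268). Other falls were AT1G22810 (-1.73 ± 0.34), DDF1 (-1.57 ± 0.31), the chloroplast beta-amylase gene CT-BMY (-1.14 ± 0.21), AT5G49280 (-1.07 ± 0.17) and AT2G35290 (-1.06 ± 0.17).

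Jasmonate genes fell in 4 of 18 cases at 1 µM, namely CYP94B3, AOC3 (-1.06 ± 0.17), LOX3 (-1 ± 0.18) and AOS (-0.99 ± 0.20), with 10 lower and 1 higher adjusted over the list alone (camera adjusted p = 1.14e-10, adjusted p = 0.097 with an estimated correlation). Photosynthesis genes rose in 4 of 38 cases, the LHCB genes above, with 10 higher and 1 lower over the list alone (adjusted p = 8.07e-08, adjusted p = 0.49 with an estimated correlation). The 4 LHCB genes have near-identical copies, so their separate values are uncertain, and summed over the family LHCB2 was at 0.98 ± 0.19 (adjusted p = 0.057) and LHCB1 at 0.47 ± 0.16 (adjusted p = 0.431). Of the singlet oxygen markers 1 of 15 fell, LOX3, and 6 over the list alone (adjusted p = 1.19e-05, adjusted p = 0.416 with an estimated correlation). ZAT10 was at -0.69 ± 0.22, ERF4 at -0.49 ± 0.13 and BAP1 at -0.77 ± 0.25, each past no threshold over all genes.

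Heat shock genes at 1 µM held 0 of 16 calls by edgeR over all genes but 8 lower over the list alone (adjusted p = 7.39e-11, adjusted p = 0.202 with an estimated correlation), HSP17.6C at -1.89 ± 0.39 and HSP70 at -1.29 ± 0.27 among them. Flavonoid genes held 0 of 5 calls and 0 over the list alone (adjusted p = 0.00023 lower, adjusted p = 0.222 with an estimated correlation), with FLS1 at -1.20 ± 0.50. Camera placed 6 further lists lower, detoxification (adjusted p = 0.0193, adjusted p = 0.635 with an estimated correlation), ethylene and ERF factors (0.0193, adjusted p = 0.552 with an estimated correlation), touch and calcium (0.0178, adjusted p = 0.306 with an estimated correlation), abscisic acid, dehydration and cold (0.0328, adjusted p = 0.306 with an estimated correlation), endoplasmic reticulum stress (0.0276, adjusted p = 0.648 with an estimated correlation) and acute light (0.0419, adjusted p = 0.416 with an estimated correlation). Each held 0 calls by edgeR over all genes. Over the list alone the lower members numbered 1, 3, 1, 1, 3 and 0. Dark and starvation genes (0.0276, adjusted p = 0.416 with an estimated correlation) and root markers (0.0193, adjusted p = 0.552 with an estimated correlation) were placed higher, with 0 calls over all genes or over the list alone.

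In total 19 genes were called at 1 µM, 5 higher and 14 lower, 12 of them changed at least 2-fold. The count was 81 by DESeq2 and 56 with the spread of the 12 libraries other than 100 µM, and in that fit the code digit as a term lowered it to 39. It was 11 with upper quartile factors, 8 after thinning and 7 without genes that have a near-identical copy, all 7 lower. Only 4 of the 19 genes have such a copy, so most of the lost calls, that of PIP3 among them, were of genes without one. The count ranged from 1 (without 1 µM replicate 3) to 9 (without control replicate 1 or 1 µM replicate 2) when any 1 library was left out.

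**Figure D3:**
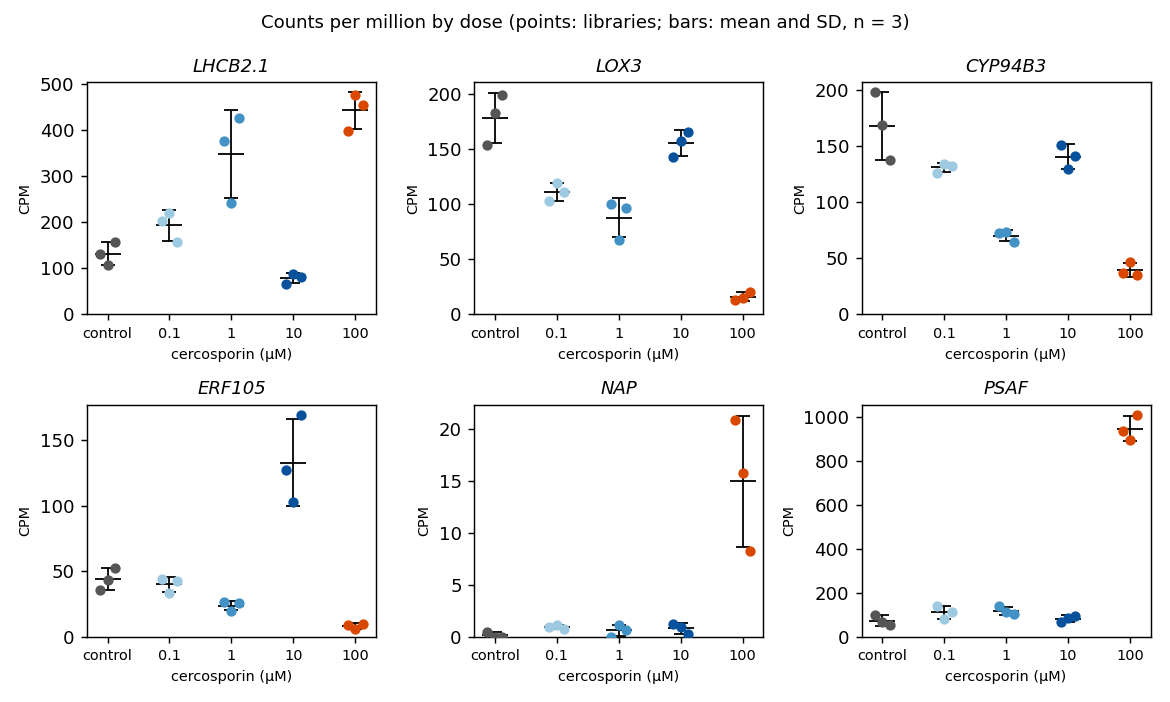
CPM of LHCB2.1, LOX3, CYP94B3, ERF105, NAP and PSAF by cercosporin dose (µM), 1 point per library, with bars for the mean and SD (n = 3 per group). LOX3 lies at 178 ± 22.8 CPM in the controls and 16.1 ± 4 at 100 µM, and ERF105 at 43.9 ± 8.21 in the controls and 133 ± 33.5 at 10 µM.

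At 10 µM, the ethylene response factor gene ERF105 (AT5G51190) was the single gene called against the controls. It rose from 43.9 ± 8.21 to 133 ± 33.5 CPM (SD, n = 3 per group), a log2 change of 1.60 ± 0.21 with adjusted p = 0.00635. Ethylene and ERF genes held 1 rise among 13 and 2 over the list alone (camera higher, adjusted p = 0.00118, adjusted p = 0.416 with an estimated correlation), with ERF104 at 0.93 ± 0.21 and ERF2 at 0.54 ± 0.21. Singlet oxygen markers held 0 of 15 calls by edgeR and 0 over the list alone, with ERF5 at 0.86 ± 0.34, ERF6 at 0.62 ± 0.26 and ZAT10 at 0.54 ± 0.21 (camera higher, adjusted p = 0.0314, adjusted p = 0.648 with an estimated correlation). Mitochondrial dysfunction genes held 0 of 6 calls and 1 lower over the list alone, AOX1A being at -0.73 ± 0.22 (adjusted p = 0.0225, adjusted p = 0.552 with an estimated correlation).

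At an unadjusted p under 0.05, 560 genes passed for 10 µM against the controls, and DESeq2 called 4 and limma-voom 1. ERF105 lost its call after thinning (adjusted p = 0.194), with only both compared groups in the fit (0.0922), with the code digit as a term (0.107), without control replicate 2 (0.0744) and without 10 µM replicate 3 (0.0979). With the digit term, 10 µM is in effect compared with the 1 control library of the same digit. Over all alternatives the log2 change of ERF105 lay between 1.38 and 1.76.

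At 0.1 µM no gene was called by edgeR against the controls, with 573 genes at an unadjusted p under 0.05; DESeq2 and limma-voom called 0 as well. The jasmonate list held 3 lower over the list alone (camera adjusted p = 4.96e-05, adjusted p = 0.222 with an estimated correlation), with LOX3 at -0.68 ± 0.18 and AOS at -0.59 ± 0.19 (SE, n = 3 per group). Camera also placed singlet oxygen markers (adjusted p = 0.00156, adjusted p = 0.589 with an estimated correlation), flavonoid genes (0.000726, adjusted p = 0.222 with an estimated correlation) and acute light genes (0.0419, adjusted p = 0.416 with an estimated correlation) lower, with 1, 1 and 0 members lower over the list alone. Root markers (0.00201, adjusted p = 0.416 with an estimated correlation) and photosynthesis genes (0.0184, adjusted p = 0.663 with an estimated correlation) were placed higher. LHCB1.1 was at 1.02 ± 0.20, but the sum over the LHCB1 family at 0.28 ± 0.16 (adjusted p = 0.927). Without the 100 µM libraries 0 genes were called by edgeR, and with the code digit as a term in that fit 7.

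Comparisons between doses share 1 light regime, but those of 10 or 100 µM with another dose coincide with the digit of the sample codes. From 1 to 10 µM, 4 of 18 jasmonate genes and 3 of 13 ethylene and ERF genes rose, while 3 of 6 extensins and 5 of 15 light-harvesting genes fell. Camera gave adjusted p = 0.28, adjusted p = 0.347 and, for the photosynthesis list, adjusted p = 0.572 with an estimated correlation. ERF105 rose from 23.8 ± 3.76 to 133 ± 33.5 CPM (SD, n = 3 per group; log2 change 2.45 ± 0.23, adjusted p = 3.31e-05), AOC3 by 1.34 ± 0.17 and ERF13 by 1.95 ± 0.30. LHCB2.1 fell from 348 ± 96.2 to 78.6 ± 11.6 CPM (-2.15 ± 0.21, adjusted p = 4.54e-05), and the cell wall extensin gene EXT10 had a log2 change of -3.34 ± 0.56. Apart from list members, genes in dose comparisons were chosen after their values were seen.

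Of the singlet oxygen markers, 4 of 15 rose from 1 to 10 µM, namely ZAT10 (1.23 ± 0.22), BAP1 (1.13 ± 0.25), LOX3 (0.81 ± 0.18) and ERF4 (0.64 ± 0.13), and 9 over the list alone (camera adjusted p = 3.66e-08, adjusted p = 0.349 with an estimated correlation). Jasmonate genes rose in 4 of 18 cases, 11 over the list alone (adjusted p = 2.79e-08, adjusted p = 0.28 with an estimated correlation). Photosynthesis genes fell in 5 and rose in 1 of 38 cases, 11 and 1 over the list alone (adjusted p = 8e-06, adjusted p = 0.572 with an estimated correlation). Root markers fell in 1 of 12 cases, TIP2;3 at -1.73 ± 0.38, and 4 over the list alone (adjusted p = 0.000837, adjusted p = 0.349 with an estimated correlation). Heat shock genes rose in 1 of 16 cases, HSP17.6C at 1.66 ± 0.39, and 7 over the list alone (adjusted p = 1.45e-07, adjusted p = 0.347 with an estimated correlation), and ethylene and ERF genes in 3 of 13, 5 over the list alone (adjusted p = 6.57e-06, adjusted p = 0.347 with an estimated correlation). Flavonoid genes were placed higher (adjusted p = 0.0314, adjusted p = 0.349 with an estimated correlation) and dark and starvation genes lower (adjusted p = 0.0111, adjusted p = 0.349 with an estimated correlation).

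In total 92 genes differed between 1 and 10 µM, 59 higher and 33 lower. The count was 209 by DESeq2, 270 with only both groups in the fit, 232 with the spread of the 12 libraries and 36 after thinning. In the 12-library fit the code digit as a term lowered the count from 232 to 11. With that term the comparison depends on the 1 control library whose code begins with 8. The fall therefore does not tell an effect of the digit from a loss of precision. With 1 library left out, the count of the main fit lay between 14 (without 1 µM replicate 3) and 67 (without 10 µM replicate 2).

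From 10 to 100 µM, 12 of 15 singlet oxygen markers fell with 0 rises, as many as over the list alone (camera adjusted p = 8.9e-05, adjusted p = 0.43 with an estimated correlation). LOX3 fell by 3.22 ± 0.21 on the log2 scale (SE, n = 3 per group) and ERF105 had a log2 change of -3.92 ± 0.26. Senescence genes rose in 4 of 6 cases (camera adjusted p = 0.0365, adjusted p = 0.349 with an estimated correlation), dark and starvation genes in 5 of 6 (0.0197, adjusted p = 0.349 with an estimated correlation) and endoplasmic reticulum stress genes in 5 of 10, 6 over the list alone (0.0138, adjusted p = 0.611 with an estimated correlation). Jasmonate genes rose in 2 and fell in 9 of 18 cases (0.0138, adjusted p = 0.351 with an estimated correlation). In total 3953 genes differed, 2163 higher and 1790 lower, and 1710 after thinning.

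From 0.1 to 100 µM the largest rises included AT3G15450 (4.52 ± 0.24, SE, n = 3 per group), the photosystem I subunit gene PSAH2 (4.32 ± 0.29), DI19 (4.28 ± 0.25), GDH2 (3.56 ± 0.31) and PIP3 (3.43 ± 0.22). The largest falls were ATCG00640 (-6.32 ± 0.50), DDF1 (-4.34 ± 0.43), AT2G35290 (-3.68 ± 0.20), the expansin-like gene EXLA2 (-3.56 ± 0.21), AT1G56045 (-3.48 ± 0.43) and AT1G22810 (-3.40 ± 0.45). Senescence genes rose in 4 of 6 cases (4 over the list alone), with NAP at 3.88 ± 0.58 (camera adjusted p = 0.0419, adjusted p = 0.349 with an estimated correlation). Endoplasmic reticulum stress genes rose in 7 of 10 (7 over the list alone, adjusted p = 0.00711, adjusted p = 0.572 with an estimated correlation) and dark and starvation genes in 5 of 6 (5 over the list alone, adjusted p = 0.0419, adjusted p = 0.39 with an estimated correlation), although these groups had the same dark step. Singlet oxygen markers fell in 5 of 15 cases, 7 over the list alone (adjusted p = 0.0314, adjusted p = 0.685 with an estimated correlation). In total 3689 genes differed, 2044 higher and 1645 lower, and 1413 after thinning.

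From 0.1 to 10 µM, 11 genes differed, 2 higher and 9 lower. ERF105 (1.72 ± 0.21, SE, n = 3 per group) and AT3G28270 rose, while EXT10 (-3.49 ± 0.54), EXT6, FTM1, PRP3, XTH14, LHCB2.1 (-1.29 ± 0.21), AT5G57625, AT1G36060 and AT1G62510 fell. LHCB2.1 has a near-identical copy, and summed over the family LHCB2 was at -0.63 ± 0.19 (edgeR adjusted p = 0.34), so its separate value is uncertain. Root markers held 0 of 12 calls by edgeR but 7 lower over the list alone (camera adjusted p = 1.62e-06, adjusted p = 0.347 with an estimated correlation). Camera placed singlet oxygen markers (6.55e-08, adjusted p = 0.349 with an estimated correlation), ethylene and ERF genes (1.62e-06, adjusted p = 0.347 with an estimated correlation), jasmonate genes (1.51e-05, adjusted p = 0.347 with an estimated correlation) and flavonoid genes (0.0419, adjusted p = 0.351 with an estimated correlation) higher. Over the list alone 7, 7, 3 and 0 of them were higher. Photosynthesis genes were placed lower, with 3 lower and 1 higher over the list alone (0.0309, adjusted p = 0.864 with an estimated correlation).

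The count for 10 against 0.1 µM was 42 by DESeq2, 18 by limma-voom, 44 with only both groups in the fit, 33 with the spread of the 12 libraries and 2 with the code digit as a term in that fit, 2 after thinning and 1 to 4 with any 1 of the 6 libraries left out. Between 0.1 and 1 µM edgeR called 0 genes, with 688 at an unadjusted p under 0.05; DESeq2 called 15 and limma-voom 0. Heat shock genes were placed lower at 1 µM, 7 of 16 over the list alone (camera adjusted p = 9.31e-08, adjusted p = 0.347 with an estimated correlation). Jasmonate genes were placed lower as well, 2 of 18 over the list alone (0.00425, adjusted p = 0.349 with an estimated correlation), with AOC3 at -0.99 ± 0.17 but not past the threshold. Photosynthesis genes were placed higher, 3 of 38 over the list alone (0.000527, adjusted p = 0.679 with an estimated correlation).

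Across the 12 treated libraries, the slope on the logarithm of dose passed for 1382 genes, 1140 rising and 242 falling. The rising share was 82.5%, against 55.4% higher among the genes called for 100 against 0.1 µM. The slopes thus do not give the balance of directions at 100 µM. Rising slopes per 10-fold dose were 1.55 ± 0.23 for AT3G15450, 1.51 ± 0.31 for NAP, 1.11 ± 0.16 for RNS1 and 0.40 ± 0.086 for CNX1 (SE, 12 libraries), whereas LOX3 (-0.47 ± 0.27) did not pass. Endoplasmic reticulum stress genes rose in 5 of 10 cases and 7 over the list alone (camera adjusted p = 0.00464, adjusted p = 0.557 with an estimated correlation). Ribosomal protein genes were placed lower, with 1 rising and 1 falling slope among 24, and 4 and 8 over the list alone (0.0483, adjusted p = 0.656 with an estimated correlation). Without the 100 µM libraries 0 genes were called by edgeR, so the trend rests on that dose and does not show a gradual change. The count was 917 with the replicate block, 877 by limma-voom, 453 after thinning, 652, 663 and 493 without replicate 1, 2 or 3 of 100 µM, and 2282 without 10 µM replicate 3. Any difference among the 5 groups was found for 3262 genes, and for 1298 after thinning.

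Of the 19 genes called at 1 µM, 18 were called in the same direction at 100 µM and 1 in the opposite direction, AT5G05600. Both comparisons share their controls. In 20 simulations with no effect at any dose, at most 1 gene was shared. That setting lacks the many genes that differ at 100 µM. It therefore cannot give the overlap that shared controls alone would produce. Independent lists would share 0.904 higher and 2.05 lower, a value that leaves out the shared controls too. The covariance of fold changes across genes was 0.152 against 0.0782 simulated (r = 0.27 against 0.48). Against 100 relative to 0.1 µM, which shares no library with 1 µM against the controls, 15 of the 19 were called the same way and 1 the opposite way, where independent lists would share 3.21 (r = 0.09). ERF105, called at 10 µM, was called in the opposite direction in both comparisons with 100 µM.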

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

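The tests below were written before their result was seen, except that those on 3'-end overlap, on reads counted differently, on samples handled apart, on exchanged labels and on reads shared among LHCB copies were chosen after the result was seen. The test of the light-harvesting genes against root share was chosen afterwards as well. The statement of the pattern of very large changes was also reworded after PSAF and PSAH2 had been seen.

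A set of 16 genes, each called at 1 or 10 µM against the controls, also differed between both doses, mostly because the change at 1 µM was small or absent at 10 µM. The difference was taken from the contrast of 10 against 1 µM, which uses the same libraries by which the genes were chosen, so an extreme value at 1 µM would raise both. ERF105 had the largest difference on the log2 scale, 2.45, from -0.85 at 1 µM to 1.60 at 10 µM. AT1G22810 differed by 2.18, AOC3 by 1.34, CT-BMY by 1.33, AOS by 1.18 and CYP94B3 by 1. Smaller differences were those of AT5G49280 (0.96), LOX3 (0.81), AT5G05600 (0.78), AT3G17800 (0.77), AT2G35290 (0.75) and LEA14 (0.66). The light-harvesting genes differed the other way, LHCB2.1 by -2.15, LHCB1.1 by -1.94, LHCB2.2 by -1.56 and LHCB1.2 by -0.91. LOX3 did not change in order of dose, at -1, -0.2 and -3.41 against the controls at 1, 10 and 100 µM. LHCB1.1 stood at 2.00, 0.06 and 1.41, but the sum over the LHCB1 family at 0.47, -0.08 and -0.01, with adjusted p = 0.431, 0.99 and 0.963, so the values of that single copy are uncertain.

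The size of the 100 µM response, 3392 genes, was weighed against technical explanations. Differing depth left 1364 genes after thinning, removal of organelle genes 3371, and 3197 of the calls remained after a fit without the genes that have a near-identical copy. Depth thus does not remove the response. The fits without organelle genes and without copies could hardly lower the count, because they left out few genes. Organelle genes were 53 of those tested, and 4.17% of the tested genes had a copy. Both fits show only that most calls lie in other genes. Samples handled, prepared or sequenced apart could also produce it: the code digit of the 100 µM libraries was shared with 0 libraries of other groups, so that explanation stays open. Exchanged group labels could also change what the response stands for. The deposited group numbers follow the order of the labelled doses in 0 of 5 groups and that of the sample codes in 5 of 5. Numbers in code order are no evidence of an exchange, but no value decides whether the labels are right.

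Very large changes were found at 100 µM, 434 genes at 8-fold or more, 369 higher and 65 lower, single members of protein complexes among them. Near-identical copies were held by 5.15% of those with a transcript in the reference (22 of 427, 95% interval 3.26% to 7.7%) against 4.12% of the others (Fisher p = 0.32), so shared reads are not a likely source. A 3' end inside another gene was held by 29.5% (126 of 427, 95% interval 25.2% to 34.1%) against 23.9% (Fisher p = 0.00932), an excess that may account for a part of the set, but most of these genes had no such overlap. Reads placed or counted differently could explain PSAF and PSAH2, the only 2 of 62 photosynthesis and ribosomal genes at that size, where the median of the 62 was -0.02; this stays open.

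The difference of extensins, LHCB genes and 1 of 12 root markers, TIP2;3, between 1 and 10 µM was weighed as a smaller share of root tissue in the 10 µM samples. The 10 root markers outside root hairs had a median of -0.51 (range -1.73 to 0.10), and root hair markers a median of -1. The first reaches the bound set beforehand by a margin inside its own spread. Against the controls, the markers outside root hairs had medians of 0.37, 0.4 and -0.13 at 0.1, 1 and 10 µM. The contrast therefore does not tell which of the compared groups is displaced. For the 5 called light-harvesting genes, less root would mean a rise, but all 5 were lower (median -1.56), so a smaller root share does not account for that part. For the root part it stays open. Reads shared among LHCB copies could not explain 1 of the 5, LHCA4, which has no copy. Summed over each family, LHCB1 was at -0.55 ± 0.16 (adjusted p = 0.122) and LHCB2 at -1.25 ± 0.19 (adjusted p = 0.00531), so the fall of LHCB2 does not rest on reads moving between its copies, whereas for LHCB1 the question stays open.

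Group labels were also regrouped. For each pair of groups there are 10 splits, too few for a share under 0.05. The real grouping gave 19 calls at 1 µM against 0 at most in another split, 1 against 0 at 10 µM, 3392 against 0 at 100 µM and 0 against 1 at 0.1 µM. Between doses it gave 0 against 0 for 1 and 0.1 µM, 92 against 0 for 10 and 1 µM, 3953 against 0 for 100 and 10 µM, 11 against 0 for 10 and 0.1 µM, and 3689 against 0 for 100 and 0.1 µM. Over 100 splits, the real trend called 1382 genes against at most 1332, and any difference 3262 against at most 3013; in both cases 1 split, the real one, reached that count. These counts make chance unlikely only for the separation of the 100 µM libraries, and not for the grouping of the other libraries or the order of the doses. The split with 1332 calls put the 100 µM libraries together at the lowest dose, and the split with 3013 also kept them together, so both counts rest on the separation of that group.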

How the results depend on the processing

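Alternatives were run for every comparison. The thinning, the removal of near-identical copies, the 12-library spread and the trend without 100 µM were chosen after the data had been seen. Counting molecules by unique identifiers was planned but not run, because the table has no such columns.

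With upper quartile factors 1 µM against the controls called 11 genes instead of 19, and without near-identical copies 7. Thinning to 834190 counts gave 8 at 1 µM, 0 at 10 µM, 1364 at 100 µM, 36 for 10 against 1 µM, 1710 for 100 against 10 µM, 2 for 10 against 0.1 µM, 1413 for 100 against 0.1 µM, 453 for the trend and 1298 for any difference, so depth limits all of these counts. Limma-voom called 877 for the trend and 18 for 10 against 0.1 µM. DESeq2 called 81 at 1 µM, 4 at 10 µM, 15 for 1 against 0.1 µM, 209 for 10 against 1 µM, 42 for 10 against 0.1 µM and 2073 for the trend. Fits of only the compared groups gave 27, 0, 2223, 17, 270 and 44 for 1, 10 and 100 µM against the controls, 1 against 0.1 µM, 10 against 1 µM and 10 against 0.1 µM. The 12-library spread gave 56 at 1 µM, 4 at 10 µM, 3 for 1 against 0.1 µM, 232 for 10 against 1 µM and 33 for 10 against 0.1 µM. With the code digit as a term and without the 100 µM libraries, 0.1, 1 and 10 µM gave 7, 39 and 1, the last a gene other than ERF105, against 0, 56 and 4 in the 12-library fit without the term. The same term, added for the dose comparisons after the data had been seen, gave 3 for 1 against 0.1 µM, 11 for 10 against 1 µM and 2 for 10 against 0.1 µM, against 3, 232 and 33. Without the 100 µM libraries the trend called 0. The digit term is estimated from the controls alone, 2 libraries with 7 and 1 with 8. A loss of precision could thus lower the counts that involve 10 µM without any effect of the digit. The cause of these differences was not tested.

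With 1 library left out, calls ranged from 0 to 0 at 0.1 µM, 1 to 9 at 1 µM, 0 to 3 at 10 µM and 3004 to 3561 at 100 µM. Between doses they ranged from 0 to 0 for 1 and 0.1 µM, 14 to 67 for 10 and 1 µM, 3411 to 4154 for 100 and 10 µM, 1 to 4 for 10 and 0.1 µM and 3095 to 3900 for 100 and 0.1 µM. The trend ranged from 493 to 2282. No named gene that was called in the main fit or in an alternative changed direction between them. A change of sign in a gene called in neither fit was counted below as a case that stayed. Genes that an alternative did not test were left out.

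The replicate number as a block gave 0, 16, 1 and 3469 genes for 0.1 to 100 µM against the controls, 99 for 10 against 1 µM, 917 for the trend and 3324 for any difference. It changed 4 list calls against the controls and 1 between doses. The acute light list lost its call at 0.1 µM (camera adjusted p = 0.0602) and 1 µM (0.0587). Mitochondrial dysfunction genes at 0.1 µM (0.0326), salicylate and immune genes at 10 µM (0.0405) and abscisic acid genes for 10 against 1 µM (0.0426) passed. Without the block, camera with an estimated correlation called 0 lists in each of these comparisons. Over 30 pairs of libraries that share a number across groups, the correlation lay at -0.14 to 0.27, 6 above 0.1, with the own number best in 10, so the numbers do not pair libraries.

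For each named gene and alternative, it was counted whether the gene was called or not, as in the main fit. Sizes of change were not compared. At 1 µM this status stayed in 891 cases, a call was lost in 88 and gained in 21. The counts were 391, 0 and 1 at 0.1 µM, 204, 5 and 0 at 10 µM, and 494, 13 and 0 at 100 µM. For 100 against 0.1 µM they were 461, 12 and 0. At 0.1 µM the main fit called 0 genes and at 10 µM 1, so cases that stayed there are mostly genes that remained uncalled.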

Other observations

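Cell wall families were examined after the values had been seen, so their members are counted without a test of the family. Arabinogalactan proteins, glycoproteins of the cell surface, fell in 14 and rose in 1 of 20 cases at 100 µM against the controls (median log2 change -1.51). The falls included AGP18 (-3.40 ± 0.20), AGP12 (-3.00 ± 0.47), AGP2 (-2.85 ± 0.20) and AGP1 (-2.70 ± 0.18), and the rise was AGP16 (1.42 ± 0.33). Expansins fell in 5 and rose in 1 of 18 cases, EXLA2 at -3.64 and EXLA3 at -3.44. Xyloglucan endotransglucosylase genes rose in 5 and fell in 5 of 18 cases, XTH24 at 2.49 and XTR6 at -3.04.

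Some extensins differed between doses. From 1 to 10 µM, 3 of 6 fell, EXT10, EXT11 and EXT6, which has a near-identical copy (median of the 6, -2.19), and from 0.1 to 10 µM 2 of 6 (median -2.17). From 10 to 100 µM 3 of 6 rose, and 4 of 12 root markers rose there with 0 falls (list median 0.68, camera adjusted p = 0.12, root hair markers at a median of 1.39). A difference in root share was not tested for that comparison. From 0.1 to 100 µM 2 of 6 extensins fell. Against the controls edgeR called 0 of 6 at each dose.

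Genes of the chloroplast and mitochondrial genomes did not all move by the same amount at 100 µM against the controls. Organelle counts were planned as a sign of RNA quality and library composition. Their changes, that of ATCG00640 included, need not reflect expression in the organelles. Of 53 tested, 23 fell and 5 rose, with a median log2 change of -1.03, an SD of 1.88 across genes and a range from -6.12 (ATCG00640) to 3.18.

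In the authors' deposited comparisons, 18 genes had an adjusted p under 0.05 at 0.1 µM, 109 at 1 µM, 13 at 10 µM and 3546 at 100 µM against the controls, where edgeR found 0, 19, 1 and 3392 here, and DESeq2 0, 81, 4 and 3542. Between doses the deposited counts were 19 for 1 and 0.1 µM, 151 for 1 and 10 µM, 101 for 0.1 and 10 µM, 4375 for 100 and 10 µM and 4003 for 100 and 0.1 µM, where DESeq2 found 15, 209, 42, 4371 and 4002 here. The names of the deposited groups did not run in order of dose, so these counts rest on the matching by fold changes. The names followed the order of the sample codes, so they need not stand for a dose and do not by themselves contradict the labels. No separate check of the labels was possible from the sources used here. Wrong labels would change the identity and direction of comparisons, the 100 µM response included, but the numbering is no sign of such an error.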
